A study of Homo sapiens with 3 samples.

How the data were processed

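The deposited tables held raw whole-number counts per gene symbol for 3 HEK293 libraries, 1 table per replicate, with 5 summary lines of the read counter at the end. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was removed with a Ribo-Zero kit and libraries were made with the NEBNext Ultra Directional kit, which preserves strand. The sample titles instead call them mRNA sequencing. Per the submitters' processing notes, the tools used were Trimmomatic, TopHat2 (given as version 2.2.5) and HTSeq 0.11.2, with the hg38 build. The gene annotation, the strand option of HTSeq, read filters and read layout are not given in the sources used here. These matter for the values, because HTSeq drops a read from a gene when it lies on the strand that its option excludes, and counts it for an opposite-strand gene that overlaps the same exons. HTSeq in its usual mode also sets aside reads that align to more than 1 place, so multicopy genes are undercounted.

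The summary lines were left out of library sizes and tests. Their shares of all records were 91.2% for no feature, 6.77% for alignments that were not unique and 0.0184% for ambiguous reads (means of 3 libraries). Gene-assigned totals ranged from 289241 to 483114. At this depth a gene with no count in a library could still lie below the value of about 3 counts, or 6.86 to 9.89 CPM. The replicate number was taken from the labels and all 3 libraries formed 1 group.

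CPM values (counts per 1000000 of the library size) were computed from the deposited counts per TMM effective library size with edgeR 4.0.16 in R 4.3.3. Genes with at least 10 counts in every library were tested for variation beyond counting noise with edgeR's generalised linear model at a dispersion of 0 and an intercept alone: the deviance was compared with a chi-square distribution and p-values were adjusted by Benjamini and Hochberg's method, with a gene counted at an adjusted p under 0.05. The excess coefficient of variation of a gene was the square root of its variance minus its counting variance, divided by its mean. The common biological coefficient of variation came from edgeR's dispersion estimate. Correlations across genes used log2(CPM + 1). Fisher's exact test and the resampling were run with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

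Before the data were examined, 31 gene lists and 18 pairs of related genes were fixed, together with the rule for the genes named: the 10 with the highest mean CPM, the 10 with the largest excess coefficient of variation among genes with a mean of at least 10 CPM that passed the test, for each list its 3 highest members and up to 3 in alphabetical order with no count, and both genes of each pair. Some genes that this rule names are not reported here. Other genes were named as the opposite-strand partner of such a gene, or as members of a list that passed the test, and were chosen after their values were seen. The rank of a list was the percentile of the median CPM of its members with a count among 10000 random lists of that many genes, drawn with replacement from genes with a count, for lists with at least 3 such members. The spread of a list was compared with 10000 random lists matched on mean CPM in 20 bins, two-sided, with Benjamini and Hochberg's adjustment over the 12 lists with at least 3 tested members. Log2 ratios of pairs used a prior of 0.5 CPM.

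Gene names were matched to GENCODE release 29 on GRCh38, 23850 by name and 723 through an older symbol, which is 92.8% of 26485. Exons of all transcripts of a gene were merged and compared with the merged exons and gene bodies on the opposite strand; any exonic base counted as overlap. This annotation is a stand-in for the one used to count, and 1912 names had no match in it. The comparison with the opposite strand was chosen after the counts were seen.

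The scripts were tested on simulated counts with the real means and library sizes. Of the genes changed in replicate 2 that passed the count filter, the test for variation called 27.0% of 63 genes changed 1.5-fold, 73.8% of 65 genes changed 2-fold and 100% of 64 genes changed 4-fold, and 0.107% of 2791 unchanged genes. A simulated coefficient of variation of 0.25 was estimated as 0.233 over 2796 genes. A planted list of 11 genes lowered 3-fold in replicate 2 gave an empirical p of 0.0010 in the spread test, and 1 of 100 null lists gave a p under 0.05. In the ranking of lists, a planted high list of 15 genes lay at the 100th percentile and 1 of 100 null lists lay above the 97.5th.

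Alternatives fixed in advance were DESeq2 1.42.0 size factors or total counts in place of TMM, no count filter, a Pearson statistic, a negative binomial null, DESeq2 dispersions, other CPM thresholds and priors, CPM per kilobase of exon, a protein-coding background, removal of ribosomal and small RNAs from the denominator and leaving out each replicate. Added after seeing the data were the removal of TSIX, an overlap of at least 100 bp and the leave-one-out shares over opposite-strand exons. Mitochondrially encoded genes, a list of 13, were not analysed here.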

Results

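Gene-level read counts were analysed for 3 RNA sequencing libraries of HEK293, an established human line derived from embryonic kidney and transformed with adenovirus DNA. The series describes a single condition in triplicate, so the libraries formed 1 group (n = 3) and no contrast between groups existed. Per the protocols, total RNA was depleted of ribosomal RNA and made into libraries with a kit that preserves the strand of the transcript. The sample titles instead call the libraries mRNA sequencing, and the values below for RNAs without a poly(A) tail (small RNAs, histone mRNAs and ribosomal RNA precursor) depend on which of these is right. The labels do not say whether the replicates came from separate cultures, so every spread and p-value below describes these 3 samples and may be technical. The questions open to this design were which gene names collected the counts and which of them differed between replicates by more than counting noise.

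Counts assigned to gene names made up 2.02% ± 0.396 (SD, n = 3) of all records in the deposited tables. Gene-assigned totals were 412066 in replicate 1, 483114 in replicate 2 and 289241 in replicate 3. The tables listed 20436963, 17854147 and 15046765 records, in the same order, as falling in no annotated feature, or 91.2% ± 0.472 (SD, n = 3) of all records. Records aligned to more than 1 place formed a further 6.77% ± 0.753 (SD, n = 3). Of 26485 gene names, 14482 had a count in at least 1 library, 7738 had a count in every library and 2564 had at least 10 counts in every library. A single count equalled 2.29, 2.31 and 3.30 CPM in replicates 1, 2 and 3, so a gene with no count could still lie below 6.86, 6.92 and 9.89 CPM, the value of 3 counts in each library. The 7738 names with a count in every library were also those reaching 1 CPM there.

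TSIX, a long non-coding RNA gene on the strand opposite to XIST, held by far the most counts. TSIX (ENSG00000270641.1) lies on chromosome X from 73792205 to 73829231 on the plus strand of GRCh38, and 7498 bp of its exonic sequence is also exonic sequence of XIST, the RNA of X-chromosome silencing, on the minus strand. Counts assigned to TSIX were 73642, 137675 and 49398 in replicates 1, 2 and 3, or 21.1% ± 6.38 (SD, n = 3) of all gene-assigned counts. XIST itself received 118, 154 and 74 counts. The 10 most abundant genes of each library together held 26.7% ± 6.15 (SD, n = 3) of gene-assigned counts, and with TSIX removed the top 10 held 7.61% ± 0.411 (SD, n = 3). Binomial 95% Wilson intervals of the TSIX share ran from 17.8% to 18.0% in replicate 1, from 28.4% to 28.6% in replicate 2 and from 16.9% to 17.2% in replicate 3. These intervals and the floors above cover counting error alone.

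The next genes were TTN, the gene of the muscle protein titin, with 9067 ± 2688 CPM (SD, n = 3), and HBS1L, a translation quality control factor, with 7340 ± 1762 CPM (SD, n = 3). COX20, an assembly factor of cytochrome c oxidase, had 6345 ± 1362 CPM and ENTPD1, an ectonucleotidase, had 6307 ± 416 CPM (SD, n = 3 each). SYNC, SNX22, RNA45S5 (the ribosomal RNA precursor), UGDH-AS1 and ATP6V1C2 completed the 10 highest, between 5571 ± 892 CPM for SYNC and 4724 ± 573 CPM for ATP6V1C2 (SD, n = 3 each). COX20 lies on chromosome 1 from 244835322 to 244845057, and 3502 bp of its exons overlap exons of HNRNPU, an abundant nuclear RNA-binding protein gene on the other strand. COX20 received 2285, 3410 and 1806 counts, against 29, 18 and 41 for HNRNPU. Exons of TTN overlapped those of TTN-AS1, exons of ENTPD1 those of ENTPD1-AS1, exons of SYNC those of RBBP4, exons of SNX22 those of PPIB, exons of UGDH-AS1 those of UGDH and exons of ATP6V1C2 those of PDIA6, each on the opposite strand. HBS1L had no opposite-strand exon in the annotation used, and RNA45S5 had no match in it. Because the strand option of the read counter is not given in the sources used here, the counts of these overlapping genes are uncertain as measures of either partner, and those of RNA45S5 are uncertain because the ribosomal DNA repeats share sequence.

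**Figure D1:**
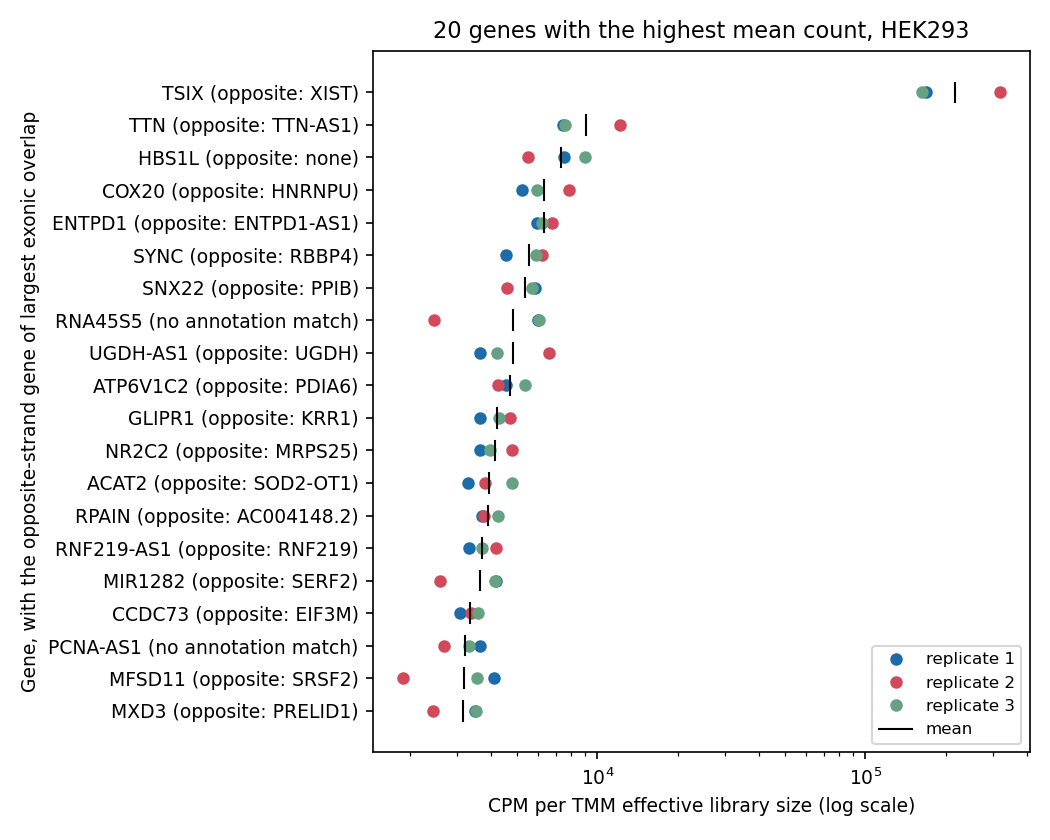
CPM per TMM effective library size (log scale) of the 20 genes with the highest mean CPM, with a coloured point for each of the 3 replicates and a black line at their mean. TSIX lies at 168339, 317350 and 162814 CPM in replicates 1, 2 and 3, apart from the other genes, and each label gives the opposite-strand gene with the largest exonic overlap.

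Gene names with an exon of another gene on the opposite strand collected most of the counts. Of the 24573 names matched to the annotation, 7795 had such an overlap, and they held 75.9% ± 1.62 (SD, n = 3) of gene-assigned counts on 40.6% of the matched exon length. The 14379 names with no gene on the opposite strand held 11.8% ± 1.19, the 2399 names over an intron only held 4.16% ± 0.499 and the 1912 unmatched names held 8.05% ± 0.874 (SD, n = 3 each). At least 10 counts in every library were reached by 21.5% of the names with exonic overlap and by 3.47% of the names with no gene opposite. Among the 50 genes with the highest mean CPM, 42 were matched and 40 of these had exonic overlap, against 31.7% of all matched names (Fisher's exact test, two-sided, p = 4.36e-18). The opposite gene was protein-coding in 32 of the 42. Of the 50, 1 belonged to a fixed list of abundant housekeeping groups: the chaperonin subunit TCP1, whose exons share 397 bp with ACAT2 on the other strand. These lists hold a small part of all names, so 1 of 50 does not show that their genes were scarce among the highest. Without TSIX the share over opposite-strand exons was 69.5% ± 1.29 (SD, n = 3).

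**Figure D2:**
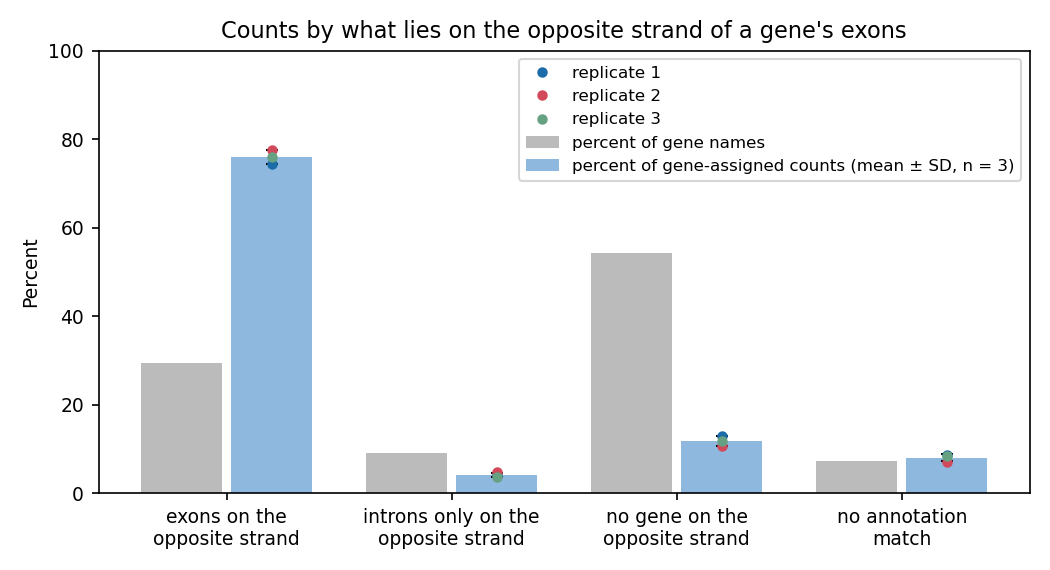
Percent of gene names (grey bars) and percent of gene-assigned counts (blue bars, mean ± SD of 3 libraries, with a coloured point per replicate), by what lies on the opposite strand of a gene's exons. Names with opposite-strand exons are 29.4% of all names and hold 75.9% of counts, while names with no gene opposite are 54.3% of all names and hold 11.8%.

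Transcripts that most human cells carry at high levels received few counts under their own names. The 78 cytosolic ribosomal protein genes together took 0.264% ± 0.0925 (SD, n = 3) of gene-assigned counts, with RPL11 at 337 ± 152 CPM, RPL10 at 217 ± 35.6 CPM and RPL9 at 192 ± 18.8 CPM (SD, n = 3 each), and with RPL17 and RPS18 among the 4 members without a count. ACTB, the cytoplasmic beta-actin gene, received 1, 0 and 1 counts, ACTG1 received 7, 0 and 2, and the tubulin genes TUBB and TUBB3 received none, which allows at most the 3-count level given above in each library. Relative to the other names with a count, some of these groups still ranked high. The median CPM of each list was taken over its members with a count, and that of the ribosomal proteins lay at the 100th percentile of 10000 random lists of as many genes with a count and that of the glycolysis list at 99.4. HK2, a hexokinase, led glycolysis with 375 ± 77.7 CPM, ahead of PFKM with 63.9 ± 20.1 CPM and ALDOA with 58.4 ± 27.2 CPM (SD, n = 3 each), and PFKL had no count. The 11 abundant small non-coding RNAs with a count lay at the 99.95th percentile, whereas the median over all 25 in the tables was 0 counts. They were led by the signal recognition particle RNAs RN7SL1 at 745 ± 516 CPM and RN7SL2 at 638 ± 402 CPM and by RN7SK, a regulator of transcription elongation, at 326 ± 225 CPM (SD, n = 3 each). RNU11, RNU12 and RNU4ATAC were among the 14 of these 25 without a count. RN7SL1 and RN7SL2 are near-identical copies and their split is uncertain.

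Nuclear long non-coding RNAs ranked at 98.5 and translation factors at 98.0, which made 5 of the 28 lists that could be ranked lie above the 97.5th percentile. KCNQ1OT1, an imprinted antisense transcript, led the first with 2684 ± 756 CPM, MALAT1 had 80.2 ± 18.8 CPM and OIP5-AS1 had 50.4 ± 9.09 CPM (SD, n = 3 each), and H19, HOTTIP and TUG1 had no count. EEF1A1 led the translation factors with 139 ± 77.4 CPM, followed by EIF2S2 at 128 ± 37.3 CPM and EEF1B2 at 127 ± 39.8 CPM (SD, n = 3 each), and EEF1A2, EEF1D and EIF3C had no count. Without replicate 3 the number of lists above the 97.5th percentile was 3, because glycolysis lay at 95.4 and translation factors at 88.3. Translation factors also lay at 91.7 without replicate 1 and at 87.6 per kilobase of exon, and nuclear long non-coding RNAs at 63.3 per kilobase.

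Cell cycle and stress groups had lower percentiles than these over all 3 libraries, and several moved when a library was left out. Spliceosome and RNA-binding genes were at the 94.4th percentile with SRSF1 at 95.4 ± 14.5 CPM, SRSF2 at 81.2 ± 35.7 CPM and HNRNPU at 81.0 ± 48.5 CPM (SD, n = 3 each), and heat shock chaperones were at 92.7 with HSP90AA1 at 446 ± 59.0 CPM (SD, n = 3). The proteasome and chaperonin list, at 86.4, was led by TCP1 with 2636 ± 214 CPM (SD, n = 3), whose exons share 397 bp with ACAT2 on the other strand. Replication-dependent histones were at 86.1, and at 100 per kilobase of exon, with HIST1H1E at 414 ± 154 CPM (SD, n = 3). The unfolded protein response was at 82.9 (DDIT3, 81.4 ± 29.2 CPM), p53 targets at 80.4 (ZMAT3, 53.4 ± 16.5 CPM) and genes of G2/M and mitosis at 79.0, where the cyclin gene CCNA2 reached 521 ± 107 CPM and TOP2A 41.0 ± 20.6 CPM (SD, n = 3 each). Cholesterol biosynthesis was at 73.5 (CYP51A1, 83.9 ± 19.2 CPM), snoRNA host genes at 72.7 (SNHG7, 48.1 ± 17.9 CPM) and DNA replication genes at 62.7 with the thymidylate synthase gene TYMS at 363 ± 49.7 CPM (SD, n = 3 each). Without replicate 1 DNA replication genes lay at 29.8, and without replicate 2 cholesterol biosynthesis lay at 53.7 and p53 targets at 58.7. Without replicate 3 snoRNA host genes lay at 33.1, histones at 50.9, G2/M and mitosis at 54.1, the unfolded protein response at 60.4 and the proteasome and chaperonin list at 61.5. Nuclear-encoded oxidative phosphorylation genes lay at 3.01, but at 19.2 without replicate 1, 0.61 without replicate 3 and 7.75 per kilobase of exon. NDUFA2 had 45.6 ± 23.4 CPM (SD, n = 3), and 6 of 27 members had no count.

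Among lineage lists, kidney development factors lay at the 1.48th percentile, but at 4.19 without replicate 1 and 14.8 without replicate 2, with HOXA11 at 36.5 ± 18.2 CPM (SD, n = 3) and with GATA3 and LHX1 among the 7 of 18 members without a count. Differentiated nephron genes were at 5.10, although PODXL, the podocalyxin gene, had 350 ± 68.1 CPM and SLC5A2, a renal glucose transporter gene, had 300 ± 54.2 CPM (SD, n = 3 each). SLC5A2 exons overlap C16orf58 on the other strand. Chromaffin genes were at 7.24 with GATA2 at 8, 6 and 3 counts, epithelial genes at 18.5 with ESRP2 at 208 ± 40.0 CPM (SD, n = 3), and neuronal genes at 21.2 with SYT1 at 30, 41 and 19 counts. Nucleic acid sensors lay at 22.7 with MAVS at 98.5 ± 52.6 CPM, immediate early genes at 25.2 with FOSL1 at 34.5 ± 10.4 CPM and pluripotency factors at 35.7 with LIN28A at 95.9 ± 28.8 CPM (SD, n = 3 each). The 5 of 18 blood and endothelial genes with a count lay at 38.9 with LYZ at 36.3 ± 14.2 CPM, 8 of 19 interferon-stimulated genes at 45.4 with IFIT1 at 105 ± 46.6 CPM, 9 of 17 mesenchymal genes at 55.5 with FN1 at 113 ± 56.2 CPM, and 6 of 12 adrenal cortex genes at 73.5 with STAR at 36.4 ± 37.8 CPM (SD, n = 3 each). Many of these places did not hold when a library was left out: without replicates 1, 2 and 3 in turn, neuronal genes lay at 32.7, 53.2 and 81.1, epithelial genes at 45.0, 14.1 and 5.56, and immediate early genes at 55.7, 6.06 and 21.5. Differentiated nephron genes lay at 3.02, 7.24 and 10.9, nucleic acid sensors at 16.8, 9.84 and 23.4, blood and endothelial genes at 56.5, 27.4 and 49.7 and mesenchymal genes at 85.0, 69.8 and 71.6, in the same order. Per kilobase of exon, epithelial genes lay at 39.1, pluripotency factors at 64.0 and mesenchymal genes at 86.5. Nucleic acid sensors lay at 11.8 and blood and endothelial genes at 21.9 on that scale. Liver genes had 2 of 12 members with a count, FGB and CYP3A4, and the ribosomal RNA list had 2, RNA45S5 and RNA28S5, too few to rank. Mitochondrially encoded mRNAs were not analysed here. These percentiles leave out members without a count, rank the rest among names with a count in these libraries and do not treat genes as replicates. Exons of 9 of the 18 kidney development factors overlapped opposite-strand exons. Because the strand option of the read counter is not given, the percentiles and CPM of these and the preceding lists describe counts under gene names. They do not show which of these genes the line expresses.

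Pairs of related genes were compared within each library, and in 10 of 18 pairs the same partner had the higher CPM in all 3 libraries. HK2 had 162, 130 and 138 counts against 2, 0 and 0 for HK1. EEF1A1 had 68, 24 and 63 counts against none for EEF1A2, and KRT8 had 27, 31 and 29 against 1, 0 and 0 for KRT18, with 525 bp of exon shared by these keratin genes on opposite strands. LIN28A exceeded LIN28B, with a log2 ratio of LIN28B to LIN28A of -2.73 ± 0.44, and LDHB exceeded LDHA, with a log2 ratio of LDHA to LDHB of -0.88 ± 0.65 (SD, n = 3 each). SLC2A1 over SLC2A3, ENO1 over ENO2, RPL22 over RPL22L1, IGF2BP1 over IGF2BP2 and NEFL over NEFM were the other 5. The order was not the same in every library, or could not be read, for PAX2 and PAX8, MYC and MYCN, CDH2 and CDH1, ZEB1 and ZEB2, MAGOH and MAGOHB, DNMT1 and DNMT3B, ACTB and ACTG1, and TUBB and TUBB3. In none of the 18 pairs did both genes have at least 10 counts in every library. With 3 libraries an exact sign-flip permutation test, two-sided, cannot give a p below 0.25, so the ratios are given without a call. Because the strand option of the read counter is not given, the order of a pair does not show which gene the cells express more.

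Replicates differed by more than counting noise at many genes, and replicate 2 stood at one end for most of them. Of the 2564 genes tested with edgeR's Poisson fit, 1175 (45.8%) had an adjusted p under 0.05; replicate 2 was highest in 579, lowest in 435 and in between in 161. It was thus at an end in 86.3% of them, where chance alone would put any given library at an end in 66.7%. The common biological coefficient of variation over the 3 libraries was 0.276, and pairwise it was 0.177 for replicates 1 and 3, 0.314 for replicates 1 and 2 and 0.294 for replicates 2 and 3. Without replicate 2, 263 of 2784 genes passed and the coefficient was 0.178. Across the 14482 genes with a count, Pearson's r of log2(CPM + 1) was 0.759 for replicates 1 and 2, 0.737 for 1 and 3 and 0.750 for 2 and 3, with Spearman's rho of 0.708, 0.684 and 0.687; genes are not independent replicates, and low counts weigh heavily here, since over genes with at least 10 counts in every library r was 0.886, 0.934 and 0.892 for these pairs in turn, highest for replicates 1 and 3. The chi-square per degree of freedom was 8.92, 3.26 and 9.40 for the same pairs, so no libraries were alike within sampling noise.

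TSIX showed the size of this difference in the most abundant gene, with replicate 2 above the mean of replicates 1 and 3 by a log2 ratio of 0.94. Among the 10 genes with the largest coefficient of variation beyond counting noise, 8 were highest in replicate 2. Over 3 libraries this measure can reach larger values for a gene high in a single library than for a gene low in a single library. The ranking therefore favours the former. Over all 1175 genes that passed, replicate 2 was highest in 579 and lowest in 435. ELK3, an ETS transcription factor gene, had 16, 84 and 11 counts (log2 ratio 2.41 for replicate 2 over the mean of the others, adjusted p = 3.42e-14), and ZNF597 had 22, 83 and 12 (2.09, adjusted p = 1.45e-11). OMD, a small proteoglycan gene, had 80, 228 and 37 counts (1.79, adjusted p = 7.34e-26) and the microtubule-associated protein gene EML4 had 23, 124 and 31 (1.89, adjusted p = 2.54e-17). MRS2P2, ARHGAP31, MBNL3 and PKIA-AS1 had log2 ratios from 1.79 to 1.96. Exons of ZNF597, OMD, MRS2P2, MBNL3 and PKIA-AS1 lay over an intron only of an opposite-strand gene, as did those of 200 of the 2564 genes tested. Those of ELK3 and EML4 overlapped opposite-strand exons, and ARHGAP31 had no gene opposite. EMILIN1 with 11, 10 and 32 counts and GGN with 16, 14 and 40 were highest in replicate 3.

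Counts under the names of small non-coding RNAs were lower in replicate 2 as a group. All 6 tested members, RN7SL1, RN7SL2, RN7SK, RPPH1, RMRP and SCARNA2, passed the test over all genes and also adjusted over the list alone, and all 6 were lowest in replicate 2; RN7SL1 had 558, 106 and 217 counts. The median coefficient of variation of this list beyond counting noise was 0.594, against 0.191 for random lists matched on mean CPM (adjusted p = 0.00240 from 10000 random lists, whose smallest unadjusted p is 0.0002), and it was the 1 list of 12 tested that passed. Without replicate 2 both medians were lower, 0.187 against 0.0677 for random lists, which put the list at the 96.5th percentile (unadjusted p = 0.0704, adjusted p = 0.986 from 10000 random lists), while the adjusted p was 0.000400 to 0.00780 under the other alternatives. The log2 ratio of its summed CPM in replicate 1 over replicate 3 was 0.60. The summed CPM of the list in replicate 2 lay below the mean of replicates 1 and 3 by a log2 ratio of -1.88. The ribosomal RNAs RNA45S5 and RNA28S5 had a summed log2 ratio of -1.29.

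Over all 2564 genes tested, 45.8% passed, and of the 1175 that did, replicate 2 was lowest in 435 and highest in 579. Of 17 ribosomal protein genes tested, 8 passed over all genes and 8 adjusted over the list alone, and 5 of those passing over all genes, among them RPL7 and RPS14, were lowest in replicate 2 and 0 were highest. All 4 tested translation factors passed under both adjustments, with EEF1A1 and EIF4E lowest and EEF1B2 and EIF2S2 highest in replicate 2. Of 6 spliceosome and RNA-binding genes, 3 passed over all genes (SRSF2, HNRNPC and HNRNPU) and 3 adjusted over the list alone, with 2 lowest and 0 highest in replicate 2 among the former. Of 5 glycolysis genes 2 passed over all genes (HK2 and ALDOA), both lowest in replicate 2, and 3 adjusted over the list alone. Summed CPM in replicate 2 over the mean of replicates 1 and 3 gave log2 ratios of -0.77 for ribosomal proteins, -0.85 for histones, -0.76 for the unfolded protein response, -0.72 for oxidative phosphorylation and -0.64 for glycolysis. The ratio was 0.60 for nuclear long non-coding RNAs, 0.44 for mesenchymal genes, 0.42 for p53 targets, 0.36 for interferon-stimulated genes and 0.22 for cholesterol biosynthesis, but per total counts 0.36, 0.21, 0.18, 0.12 and -0.01 in the same order. It lay between -0.41 and 0.15 for the lists not named here or above that had at least 50 counts in every library, some of which changed sign per total counts. None of these ratios was tested. KCNQ1OT1, with 1140, 1508 and 598 counts, was the 1 of 3 nuclear long non-coding RNAs tested to pass, over all genes and over the list alone, and it was highest in replicate 2 (adjusted p = 3.30e-32).

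**Figure D3:**
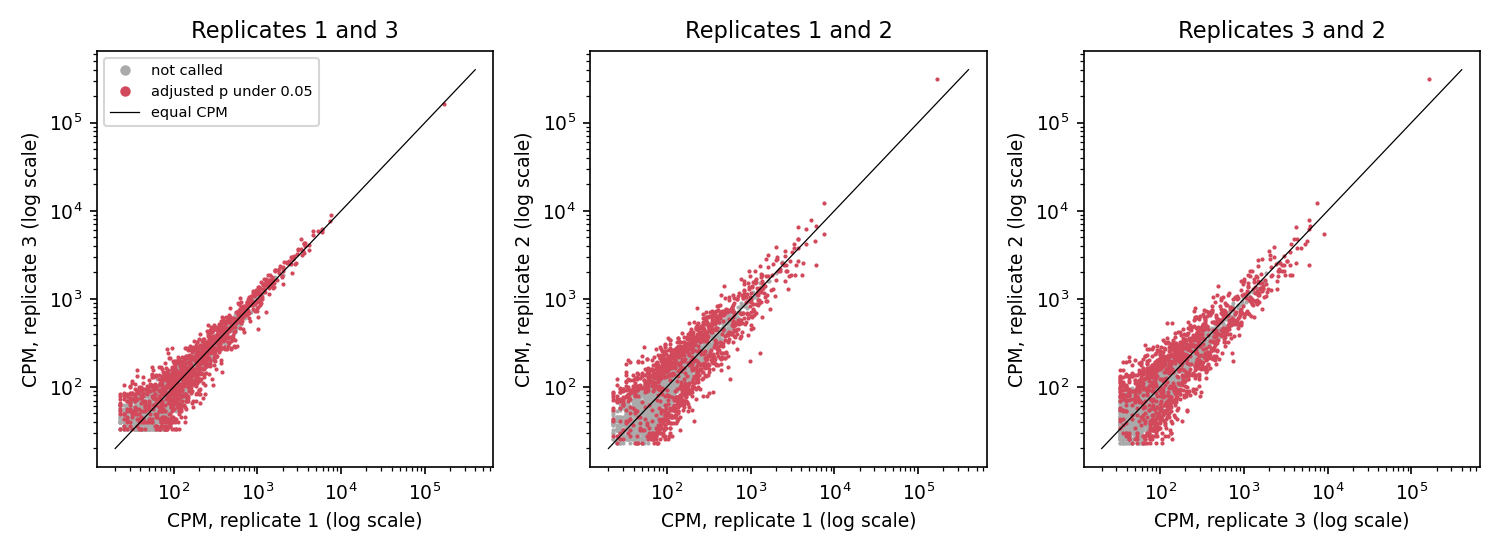
CPM of the 2564 genes with at least 10 counts in every library for each pair of replicates (both axes log scale), with genes past an adjusted p of 0.05 over the 3 libraries in red, other genes in grey and a line at equal CPM. Replicates 1 and 3 lie closer to the line (pairwise coefficient of variation 0.177) than either does with replicate 2 (0.314 and 0.294).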

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

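Records that the tables assign to no gene lie outside the report's gene comparisons and made up 91.2% ± 0.472 (SD, n = 3) of all records. Some of the tests below were chosen after the values they measure, or closely related ones, had been seen. These were the tests of the position of the highest genes, of genomic DNA, of each gene's own RNA and of low counts in genes without an opposite-strand gene. With 1 group in the design, no biological explanation was tested for any of these patterns.

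Few reads fell in genes, and those that did were led by genes that share exons with a gene on the other strand. A candidate explanation is that reads of a strand-specific kit were counted on the strand opposite to the transcripts. The 95.2% of matched genes among the 50 highest that had opposite-strand exons are the pattern itself and so do not test this, and a test written beforehand left it open: counts per shared kilobase were 2.27 times higher where the opposite gene was in an abundant housekeeping list (32 genes) than where it was another protein-coding gene (2568 genes; permutation p = 0.131, bootstrap 95% interval 1.16 to 5.15). Other accounts of the gene-assigned counts are argued against by the tables. Genomic DNA as their main source would give similar counts per exonic kilobase with and without an opposite-strand gene. The ratio without TSIX was at least 4.68 in every library. Genomic DNA among the records in no feature was not tested. Counts that were each gene's own RNA would give ribosomal protein genes at least 2% of counts in a growing cell line. Their share was at most 0.331%. RNA sequenced without strand had no test of its own. It would also give these genes counts of their own RNA, so the same share argues against it for them.

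Replicate 2 differed more from replicates 1 and 3 than those did from each other, with a ratio of the pairwise coefficients of variation of 1.72. GC content is argued against as the whole source, since the ratio was 1.61 after a loess correction for it (bootstrap 95% interval 1.52 to 1.72). That correction used the GC content of the opposite-strand gene where it shared at least 100 bp, and of the counted gene elsewhere. With the counted gene's GC content throughout, the ratio was 1.59 (1.503 to 1.683). Replicate 2's log2 ratio did fall with GC across genes (Spearman's rho -0.386 and -0.412 over 2377 genes, in the same order). Transcript length, assigned as in the first correction, is argued against too, with a ratio of 1.72 after correction (1.63 to 1.85). Each of these intervals came from 50 resamples. More unspliced RNA in replicate 2 may contribute, but only if the counts come from the opposite-strand genes, which is left open above. Genes lying over introns of an opposite-strand gene (200 genes) exceeded those over exons (1678 genes) by 0.56 in median log2 ratio (bootstrap 95% interval 0.42 to 0.71, permutation p = 2.0e-05, the smallest these permutations can give). The difference was 0.43 after a GC trend was removed. How much of the pattern unspliced RNA could cover stays open. The ratio of coefficients was 1.74 over the 1678 genes with opposite-strand exons alone, but the rest of their exons can lie over introns.

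Genes with no gene on the opposite strand still received some counts. A small share of reads on the other strand is a candidate source, since mean counts per kilobase in such genes were 3.59 times higher for the abundant housekeeping lists (111 genes) than for lists of other tissues (47 genes; permutation p = 0.000340, bootstrap 95% interval 1.19 to 22.8). The same contrast would also arise from low levels of correctly counted RNA, which this test cannot separate from it.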

How the results depend on the processing

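No paired analysis was possible because the series has 1 group. Of the alternatives, those without TSIX, those with at least 100 bp of overlap and the leave-one-out values of the share over opposite-strand exons were chosen after seeing the data. The number of genes detected (5411 to 9170) and the pairs with the same order (10 to 12) stayed within 1.5 times their values in the report under every alternative run. Genes varying beyond counting noise, 1175 in the report, numbered 2914 of 14482 with no count filter and 0 of 2564 in edgeR under a negative binomial null at the common dispersion, where 135 had an unadjusted p under 0.05; that null asks for more spread than the common one, and no other tool was run for it. Leaving out each replicate gave 263 to 1093 genes, with 263 when replicate 2 was left out. The common biological coefficient of variation was 0.482 with no count filter and 0.178 to 0.317 over the leave-one-out fits. Mean Pearson's r was 0.581 with a prior of 0.1, 0.855 with a prior of 5 and 0.904 over genes with at least 10 counts in every library. The share of the top 10 genes was 7.61% without TSIX. The share over opposite-strand exons was 71.8% with at least 100 bp of overlap and 69.5% without TSIX. Lists above the 97.5th percentile numbered 3 against a protein-coding background, in which non-coding lists drop out by construction, and 3 to 5 over the leave-one-out runs. Lists called for spread numbered 0 to 1, with 0 when replicate 2 was left out. The cause of the other shifts was not tested. At this depth a gene with no count in the library with the fewest counts could still lie below 9.89 CPM. Why 12003 of 26485 names had no count was not tested.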

Other observations

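If the counts lie on the strand opposite to the transcripts, a gene's count would report its opposite-strand partner; that is a hypothesis, prompted by the counts themselves. The test of it written beforehand, on abundant partners, gave a ratio of 2.27 and left it open (permutation p = 0.131). The counts given here are those of the whole counted gene, not of the shared exons alone, and per-kilobase values divide them by the shared length. The genes below were chosen after the counts had been seen. HMMR-AS1, opposite the mitotic gene HMMR, had 621, 648 and 561 counts in replicates 1, 2 and 3, and EXOSC9, opposite the cyclin gene CCNA2, had 219, 258 and 185, but BRD8, opposite the mitotic gene KIF20A, had 2, 2 and 0. VIM-AS1, opposite the intermediate filament gene VIM, had 1218, 563 and 745, while VIM itself had 26, 10 and 9. MFSD11, opposite the splicing factor gene SRSF2, had 1807, 818 and 1075, and GNRHR2, opposite the exon junction gene RBM8A, had 619, 575 and 493, but CBX3, opposite HNRNPA2B1, had 8, 3 and 6. All 5 spliceosome and RNA-binding partners had at least 10 counts per shared kilobase, with a median of 655, and 9 of 11 ribosomal protein partners did, with a median of 42.7. The median was 12.8 over the 2568 genes opposite a protein-coding gene outside the abundant housekeeping lists. Reaching 10 was therefore common and does not set these partners apart. FAM69A, opposite RPL5, had 257, 337 and 223 counts.

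Partners of genes of other tissues varied, and no test compared them with the partners above. None of 4 genes opposite the differentiated nephron genes NPHS1, SLC5A2 and SCNN1A reached 10 counts per shared kilobase. DBH-AS1 and HAND2-AS1, opposite the chromaffin genes DBH and HAND2, had no counts. WBP1L, opposite the steroidogenic gene CYP17A1, had 0, 2 and 2 counts over a shared 1417 bp, and GDNF-AS1, opposite GDNF, had none. Others had more: ASH2L, opposite the steroidogenic gene STAR, had 10, 14 and 2 counts, and 2 of 5 partners of kidney development factors reached 10 counts per shared kilobase, PIN4 opposite CITED1 with 14, 5 and 8 counts and MEIS1-AS2 opposite MEIS1 with 12, 7 and 2. Genes opposite the translation factors EIF2S1, EIF5A and EEF1D had a median of 2.77 counts per shared kilobase, NRDE2, which shares 4671 bp with the proteasome gene PSMC1, had 0, 1 and 0 counts, and APOA1-AS, opposite the liver gene APOA1, had 10, 9 and 0.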
